A study of Mus musculus with 16 samples.

How the data were processed

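Hearts of mice were profiled by RNA sequencing. Per the labels' protocols, RNA was extracted with a column kit and polyadenylated RNA was pulled down for a strand-preserving TruSeq library. The 16 libraries form 4 groups: adult C57 mice (n = 3), aged Hap-I mice (n = 4), aged Hap-I mice on a western diet (n = 5), and younger, adult Hap-I mice on a western diet (n = 4). Hap-I mice are C57/BL6 mice that carry haplotype I of the human angiotensin II type 1 receptor gene. The series design text says that the samples come from separate animals. It names the younger Hap-I group without a diet, whereas each of its 4 sample labels states the western diet; the sample labels were followed, and every comparison with that group is open to this conflict. The labels give no sex, litter, age in months, batch or hour of collection.

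The authors deposited 1 table of TPM, length-corrected transcript abundances, per gene for the whole series, per the file headers. TPM divide the reads assigned to a gene by its effective length and rescale each library to 1 fixed total, so they keep no sequencing depth: the depth is unknown, no counting error can be given, and errors are spreads between animals. Per the submitters' processing notes, kallisto, DESeq2 and the mouse build GRCm38 were used, with no versions stated. kallisto matches 31-base words of reads to transcripts and divides reads that fit several transcripts between them by an estimate, so genes with near-identical copies are reported as uncertain. The table holds 30153 genes, of which 29732 had a symbol in the gene name table used here and 421 did not. Its columns summed to between 942090 and 959772 TPM, so part of that fixed total lies in transcripts not analysed here. The human receptor transgene was not analysed here. The 2 genes for X inactivation were not used here.

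Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and most of the alternatives had been fixed. Genes with at least 1 TPM in at least 3 libraries were kept, 11415 in all. Values were divided by median-of-ratios size factors computed over these genes, which ranged from 0.678 to 1.231, and are called scaled TPM. One limma model with a mean for each of the 4 groups was fitted to log2(scaled TPM + 1) over all 16 libraries with a variance trend, so that the groups shared 1 estimate of each gene's spread. The 7 comparisons were contrasts of this model, the last of them the equal-weight mean of the 3 Hap-I groups minus C57. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(scaled TPM + 1) scale and understate the changes of genes at low TPM. Errors of fold changes are standard errors of the model; errors of TPM are SD.

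Of 49 gene lists fixed beforehand (pathways and cell type markers that fit heart, angiotensin signalling, age and diet), 45 had at least 3 members among the genes kept. Each was tested with limma's camera at a preset correlation of 0.01, and the p-values were adjusted over the lists within a comparison. Members called are counted over all genes tested and again adjusted over the list alone. Alternatives were camera with an estimated correlation and fry. The genes named in the text were, per comparison, the 8 genes with the largest positive and the 8 with the largest negative log2 fold change (5 each against C57) among called genes with non-overlapping groups and at least 5 scaled TPM in the higher group. To these were added 8 genes named in every comparison (Agtr1a, Agt, Ace, Nppa, Nppb, Myh7, Col1a1 and Col3a1) and the members of smallest p from called lists, up to 4 per list. Lists were taken by increasing p; after the values were seen, members of 3 further called lists (the positive arm of the circadian clock, calcium handling, and fibrosis) were added under the same rule. Some genes that these rules name are not reported here; they were left out of the counts over named genes and not replaced.

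The alternatives fixed beforehand were no scaling, quantile normalization, a scaling without mitochondrial transcripts, pseudocounts of 0.1 and 0.5, no filter, a filter at 5 TPM, no variance trend, a robust variance, library weights, a 2-fold or a stricter adjusted p threshold of 0.01, a sex covariate (absence of Y-linked transcripts) for the counts of called genes, a model of only the groups compared, and the omission of each library in turn. Chosen after the data were seen were a correction for transcript length (lowess of each library's deviations on log2 length), the same with a sex covariate, a fit of the 11 libraries with Y-linked transcripts, a covariate for atrial markers, and a fit without 2 libraries that stood apart. The atrial covariate was each library's mean log2(scaled TPM + 1) of Myl7, Myl4, Sln and Mybphl. Its refits therefore cannot test these genes or the list of atrial markers, which holds them. Of the western-diet groups, the fit of libraries with Y-linked transcripts kept only aged replicates 4 and 5 and younger replicates 3 and 4. A call lost in that fit can also come from the smaller groups. The code, not power in the real libraries, was tested on simulated data built from them, with 50 genes changed at each size. For aged Hap-I mice with against without western diet (11210 genes), 66% of 1.5-fold and 94% of 2-fold changes were recovered, with 12 false calls. For adult C57 against younger Hap-I mice (11252 genes) it was 42% and 80%, with 9 false calls. Words of 31 bases shared between genes were counted in the GRCm38 transcripts. The work used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.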

Results

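Transcript levels were measured in 16 mouse hearts: 3 from adult C57 mice, 4 from aged Hap-I mice, 5 from aged Hap-I mice on a western diet, and 4 from younger Hap-I mice that their sample labels place on a western diet. Hap-I mice carry the human angiotensin II type 1 receptor gene as a transgene, and a western diet is rich in fat and sugar. The design text lists the younger Hap-I group without a diet, so diet in that group rests on the sample labels. Between 9553 and 11175 genes reached 1 TPM in a library, and mitochondrially encoded transcripts took 29.3% to 44.2% of the TPM. No 2 libraries held identical values. Across genes, which are not independent replicates, log2 values of library pairs correlated at r = 0.956 to 0.99. Y-linked transcripts were near 0 in aged western-diet replicates 1, 2 and 3 and in younger western-diet replicates 1 and 2. They were present in the other 11 libraries, so the groups differed in this respect. Principal components 1, 2 and 3 held 24.6%, 20.7% and 9.7% of the variance. Component 3 set aged western-diet replicate 5 apart, at 35.2 against -7.1 to 6.2 in the others.

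Libraries also differed in how expression related to transcript length. The rank correlation of a library's deviation from the gene means with length ran from -0.51 to 0.55. It averaged 0.23 ± 0.31 (SD, n = 9) in libraries of aged mice and -0.26 ± 0.26 (SD, n = 7) in libraries of adult mice. Without scaling, the median log2 fold change of all genes lay at -0.16, 0.11, 0.27, 0.13, -0.13, -0.03 and -0.01 in the 7 comparisons, in the order in which they follow, and changes are reported relative to the scaled median. Atrial markers varied widely within groups: Myl7, the atrial regulatory myosin light chain, stood at 1843, 26.8 and 885 scaled TPM in the 3 C57 hearts and at 17.6 or less in all 5 aged western-diet hearts.

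**Figure D1:**
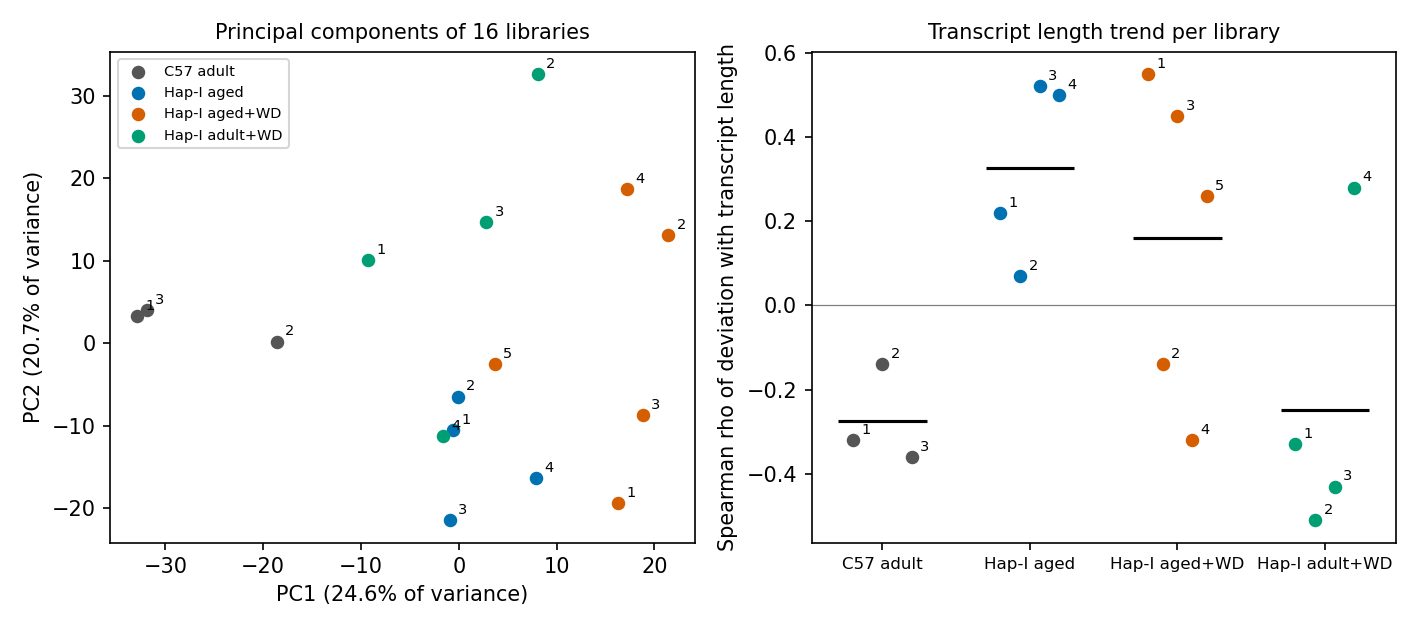
Left, each of the 16 libraries by its scores on principal components 1 and 2 of log2 scaled TPM, coloured by group. Right, each library's rank correlation between its deviation from the gene means and transcript length, with bars at the group means; libraries of adult mice averaged -0.26 and those of aged mice 0.23.

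The first comparison asked what a western diet did to the hearts of aged Hap-I mice (n = 5 with and 4 without the diet). Pdk4, a kinase that restrains glucose oxidation by blocking pyruvate dehydrogenase, rose 3.08-fold, from 33.9 ± 4.98 to 112 ± 40.3 scaled TPM (log2 fold change 1.62 ± 0.26, limma adjusted p = 0.0203). Pmepa1, a restrainer of TGF-beta signalling, and Slc25a22, a mitochondrial glutamate carrier, rose by log2 fold changes of 0.65 ± 0.12 (adjusted p = 0.0432) and 0.60 ± 0.11 (adjusted p = 0.041). The terminal complement component C7 fell from 5.89 ± 1.99 to 1.04 ± 1.02 scaled TPM (log2 fold change -1.84 ± 0.32, adjusted p = 0.0373). Kcnq1, which carries the slow delayed rectifier potassium current, fell by 0.56 on the log2 scale (adjusted p = 0.0196). Myl9, the smooth muscle regulatory myosin light chain, fell by 0.98, and Extl2, a glycosyltransferase, had a log2 fold change of -0.48 (adjusted p = 0.0429 and 0.019). Banp and Rnf44 rose by 0.90 and 0.41 (adjusted p = 0.045 and 0.041). Entpd4b fell by 0.89 (adjusted p = 0.000114), but all of its 31-base words lie in other genes, so its level is uncertain. Pdk4 (ENSMUSG00000019577) lies on chromosome 6 at 5483351 to 5496309 and C7 on chromosome 15 at 4988762 to 5063740 in GRCm38.

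In the same comparison the interferon response list moved as a group without a member that passed over all genes. All 26 tested members had positive values, 19 rose when adjusted over the list alone, and the median log2 fold change was 0.96 (camera adjusted p = 3.89e-14; adjusted p = 0.415 with an estimated correlation). The median was 0.62 without western-diet replicate 5, 1.51 with a sex covariate and 1.87 in libraries with Y-linked transcripts (diet: replicates 4 and 5). Irf7, an interferon regulator, stood at 49.7 and 72.9 scaled TPM in these replicates. It was at 6.5 to 12.7 in the other 3 and at 3.1 to 4.8 in hearts without the diet (log2 fold change 2.03, adjusted p = 0.107). Ifi27l2a and Oas2 had values of 1.55 and 1.35 (adjusted p = 0.082 and 0.0901), and Oas1a, which shares 68.8% of its 31-base words with other genes, 1.2 (adjusted p = 0.082). Of 14 glucocorticoid targets, 1 rose, 0 fell and 6 rose adjusted over the list alone, with a median of 0.59 (adjusted p = 5.73e-08; adjusted p = 0.337 with an estimated correlation). Cdkn1a and Sgk1 of that list did not pass, at 1.14 and 0.65 (adjusted p = 0.0615 for both), nor did Angptl4, an inhibitor of lipoprotein lipase, at 1.13 (adjusted p = 0.0696). Of 24 genes of cholesterol and fatty acid synthesis, 0 rose and 1 fell. Adjusted over the list alone 1 rose and 5 fell (median -0.20, adjusted p = 8.6e-05; adjusted p = 0.337 with an estimated correlation). Mvd and Idi1, enzymes of the mevalonate pathway, had values of -0.43 and -0.31 and did not pass (adjusted p = 0.0512 and 0.107), with 22.2% of the words of Idi1 shared with other genes, and Me1, malic enzyme, was at 0.39 (adjusted p = 0.113). The 6 replication-dependent histone genes, a check on the RNA since most of their transcripts lack a poly(A) tail, had 0 called over all genes and 2 risen adjusted over the list alone (median 0.39, adjusted p = 0.00364; adjusted p = 0.415 with an estimated correlation).

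Of 17 genes of the tricarboxylic acid cycle none passed over all genes and 4 fell adjusted over the list alone, with a median of -0.28 (camera adjusted p = 8.91e-05; adjusted p = 0.415 with an estimated correlation); Dld, a subunit of the mitochondrial dehydrogenase complexes, was at -0.34 (adjusted p = 0.109). The 16 ventricular cardiomyocyte markers, with 0 called over all genes or adjusted over the list alone, stood beside them at a median of -0.16 (adjusted p = 0.0313; adjusted p = 0.415 with an estimated correlation). Their call was lost without aged replicates 1, 2 or 4 (0.0585, 0.0996 and 0.0543), western-diet replicate 1 or 5 (0.061 and 0.0778), with a sex covariate (0.0612) and among the libraries with Y-linked transcripts (0.182). Of 6 Schwann cell markers 0 were called and 4 fell adjusted over the list alone (median -0.31, adjusted p = 0.00441; adjusted p = 0.415 with an estimated correlation), a call lost with the atrial covariate (0.0533) and among the libraries with Y-linked transcripts (0.0508). Of 12 pericyte and smooth muscle markers, 1 fell and 5 fell adjusted over the list alone (median -0.47, adjusted p = 0.00299; adjusted p = 0.337 with an estimated correlation). The 13 renin-angiotensin genes had 11 negative values, 0 called members over all genes or adjusted over the list alone, and a median of -0.22 (adjusted p = 0.00469; adjusted p = 0.415 with an estimated correlation). The median was -0.14 with a sex covariate, and with length and sex corrected together the call was lost (0.0537). The receptor gene Agtr1a of the mouse was at -0.37 ± 0.13 (adjusted p = 0.189), Agt at -0.25 and Ace at -0.80. The stress and matrix genes Nppa, Nppb, Myh7, Col1a1 and Col3a1 did not pass, with adjusted p from 0.342 to 0.912. The 33 fibrosis genes had 0 called members over all genes or adjusted over the list alone, with 25 negative values and a median of -0.31 (adjusted p = 0.0137; adjusted p = 0.792 with an estimated correlation). That call was lost without aged replicate 3 (0.0985), western-diet replicate 2 (0.285) or western-diet replicate 4 (0.2), where the median was -0.27, -0.16 and -0.17. It was also lost with a sex covariate (0.194; 0.249 with the length correction as well), without scaling (0.185) and among the libraries with Y-linked transcripts (0.157). With the atrial covariate the median was -0.12 and the call was lost (0.463). The 15 fibroblast markers were not called (median -0.10, adjusted p = 0.934). The 9 atrial markers, with 0 called over all genes or adjusted over the list alone, stood beside these groups at a median of -1.82 (adjusted p = 0.0137; adjusted p = 0.605 with an estimated correlation). Their call was lost without aged replicate 3 (median -0.66, adjusted p = 0.43) or western-diet replicate 5 (0.0516), without scaling (0.123) and among the libraries with Y-linked transcripts (0.157). Y-linked genes also differed, at a median of -1.73.

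In all, 19 genes passed in limma, 9 higher and 10 lower with the diet, 7 of them by 2-fold or more, and 1817 genes had an unadjusted p under 0.05 against 571 expected by chance. Without scaling the split was 4 higher and 21 lower, and with mitochondrial transcripts left out of the scaling it was 8 and 17; both lost Banp, Pmepa1, Slc25a22, Rnf44, Kcnq1 and Extl2. The count was 4, 4, 4 and 6 without aged replicates 1, 2, 3 and 4, it was 7 without western-diet replicate 2 or 3, and it was 92 without western-diet replicate 5. Of the 10 genes named here that passed, Entpd4b passed without any 1 library; for the other 9 the adjusted p reached 0.0733 to 0.154, and for Pdk4 0.087, on leaving out an aged replicate or some western-diet replicates. With a sex covariate 44 genes passed, 34 higher and 10 lower, and among the libraries with Y-linked transcripts 140, 107 higher and 33 lower; of the 19 genes, 10 and 7 were among these. With the sex covariate Pdk4, C7 and Kcnq1 were kept while Banp, Pmepa1, Slc25a22, Rnf44 and Myl9 were lost. With a covariate for atrial markers 5 genes passed, and of the named genes only Entpd4b did.

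**Figure D2:**
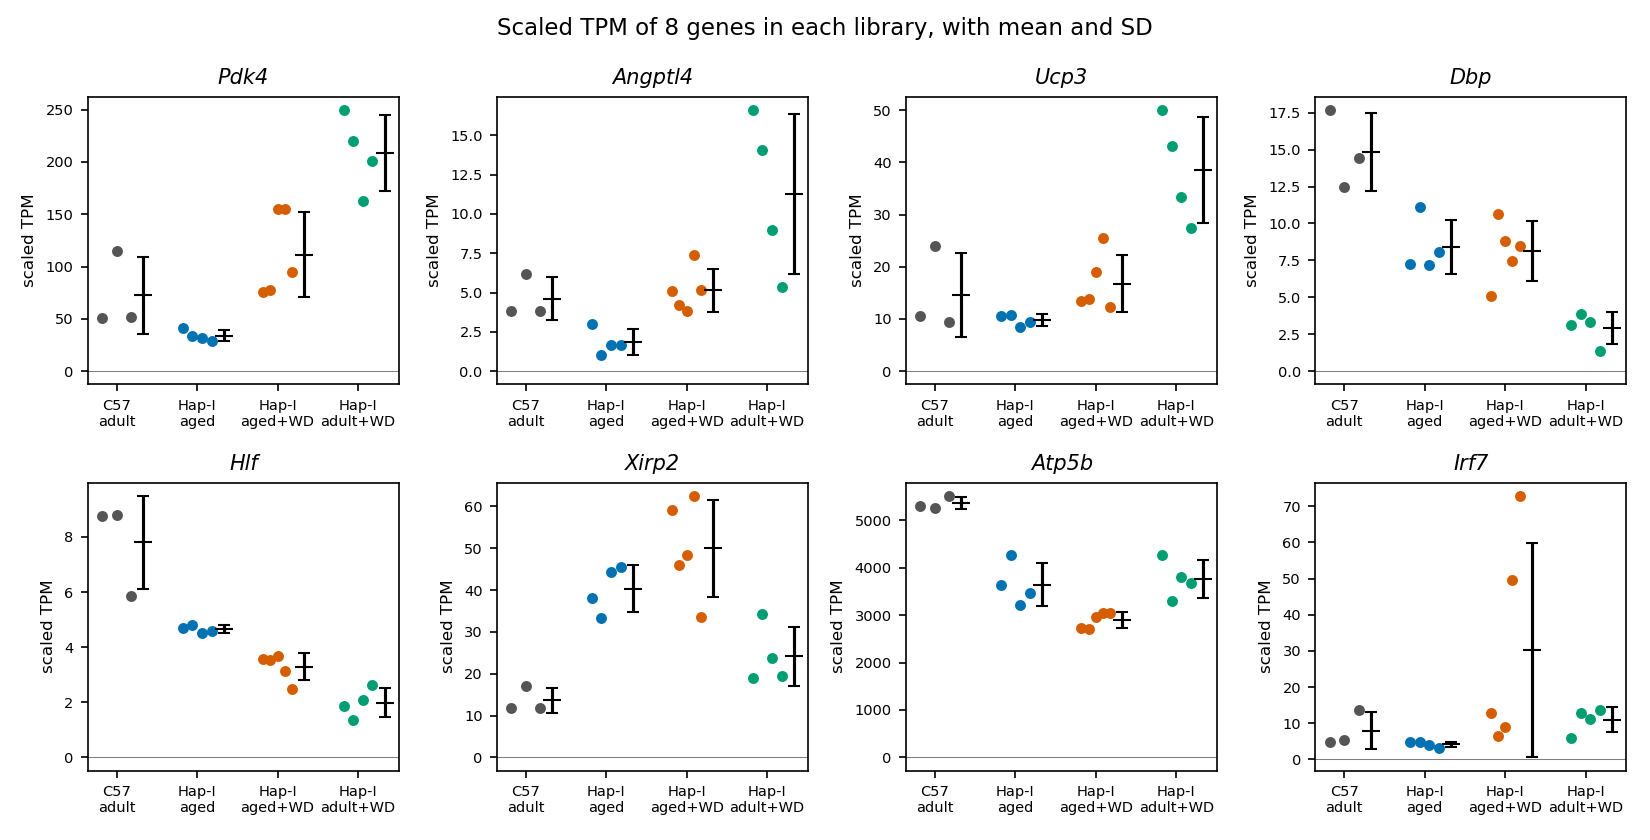
Scaled TPM of 8 genes in each of the 16 libraries, as points by group, with the group mean and SD; each panel has its own axis. Pdk4 averaged 33.9 in aged, 112 in aged western-diet and 208.5 in younger western-diet hearts, and Dbp averaged 14.9 in C57 and 2.92 in younger western-diet hearts.

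The second comparison set aged against younger Hap-I hearts, both on a western diet by their sample labels (n = 5 and 4), and addresses age under that diet. Dbp, a clock output gene and transcription factor with a strong daily rhythm, rose in the aged hearts and stood at 8.11 ± 2.03 against 2.92 ± 1.08 scaled TPM (2.35-fold, log2 fold change 1.23 ± 0.21, limma adjusted p = 0.0152), with 28.3% of its words shared with its overlapping neighbour Sphk2. Per2, a repressor of the clock, rose by 0.96 ± 0.14 (adjusted p = 0.00653), Per3 by 0.85 and Hlf by 0.53 (adjusted p = 0.0395 and 0.0451). Ucp3, a mitochondrial uncoupling protein, fell 2.25-fold, from 38.5 ± 10.1 to 16.8 ± 5.5 (log2 fold change -1.17 ± 0.25, adjusted p = 0.0261), and Ehhadh, a peroxisomal enzyme of fatty acid oxidation, fell by 0.70 (adjusted p = 0.02). Tns2, a focal adhesion protein, and Mcf2l, a guanine nucleotide exchange factor, rose 2.3-fold and 2.08-fold (adjusted p = 0.0189 for both). Cpeb1, Cds1 and Mga rose by 0.91, 0.83 and 0.83 (adjusted p = 0.0152, 0.0167 and 0.0236), and Mdm4, a p53 inhibitor with 27.6% of its words shared with other genes, by 0.85 (adjusted p = 0.0339). Pigu, a subunit of the transamidase for membrane anchors, fell by 0.58 (adjusted p = 0.00653). Nadk2, Ift81 and Myl9 fell 1.5-, 1.55- and 1.85-fold (adjusted p = 0.0348, 0.04 and 0.0225). Ahcy rose by 1.47 (adjusted p = 0.0215), and mt-Nd3 and Eif3j2 fell 3.25- and 2.15-fold (adjusted p = 0.000148 and 0.00055). These 3 share 79.4%, 98.1% and 94.3% of their 31-base words with other genes and are uncertain. Dbp lies on chromosome 7 at 45705088 to 45710203 and Ucp3 on chromosome 7 at 100472990 to 100486432 in GRCm38.

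Of 11 genes in the negative arm and outputs of the clock, 4 rose, 0 fell and 10 rose adjusted over the list alone, with a median log2 fold change of 0.53 (camera adjusted p = 3.97e-09; adjusted p = 0.13 with an estimated correlation). Of 35 genes of fatty acid oxidation and PPARalpha targets, 2 fell and 5 fell adjusted over the list alone, at a median of -0.24 (adjusted p = 1.89e-05; adjusted p = 0.933 with an estimated correlation). Quantile normalization ended this call (0.124). All 51 nuclear genes of oxidative phosphorylation had negative values, and 0 of them passed over all genes or adjusted over the list alone. Their median was -0.20 (adjusted p = 7.5e-07; adjusted p = 0.933 with an estimated correlation), -0.10 after correction for transcript length and 0.03 among the libraries with Y-linked transcripts, and its call was lost under quantile normalization (0.145). Atp5f1, Atp5b and Uqcrfs1 of this list did not pass, at -0.39, -0.38 and -0.32 (adjusted p = 0.071, 0.071 and 0.0882), with 46.7% of the words of Atp5f1 shared with other genes. All 26 interferon genes had positive values with none called over all genes or adjusted over the list alone (median 0.43, adjusted p = 0.00136; adjusted p = 0.933 with an estimated correlation). Without aged replicate 5 the call was lost (median 0.13, adjusted p = 0.318), and without aged replicate 2 the median was 0.70. The 47 ribosomal protein genes had a median of -0.12 (adjusted p = 0.0114; adjusted p = 0.933 with an estimated correlation), 0 called over all genes or adjusted over the list alone, and this median was 0.02 without scaling, 0.003 under quantile normalization, 0.02 with mitochondrial transcripts left out and 0.16 among the libraries with Y-linked transcripts. Without younger replicate 2 it was 0.01. The call was lost there (0.993), without aged replicate 1, 3 or 5 (0.221, 0.16 and 0.139) and after the length correction (0.691). Without aged replicate 2 or 4 or younger replicate 4 the median was -0.23, -0.22 and -0.30. Agtr1a was at 0.03 ± 0.13 (adjusted p = 0.911), and Agt, Ace, Nppa, Nppb, Myh7, Col1a1 and Col3a1 did not pass either.

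In this comparison 273 genes passed, 191 higher and 82 lower in the aged hearts, 19 of them by 2-fold or more; 2249 had an unadjusted p under 0.05. Log2 fold changes rose with transcript length across genes (rank correlation 0.45). After the length correction 156 genes passed, 93 higher and 63 lower. Without scaling 22 passed, and of the named genes Dbp, Cds1, mt-Nd3, Eif3j2 and Per2 were kept. With only the groups compared 5 passed, mt-Nd3 and Eif3j2 among them. The count was 108 and 79 without aged replicates 1 and 3, 28, 179 and 46 without younger replicates 1, 2 and 3, 572 without aged replicate 4 and 480 without younger replicate 4. Dbp, Cpeb1, mt-Nd3, Eif3j2, Pigu and Per2 passed without any 1 library, while the other 13 named genes that passed reached an adjusted p of 0.0543 or more without some library. Among the 11 libraries with Y-linked transcripts (2 against 2) 12 genes passed, 5 of the 273. Of the 19 named genes mt-Nd3 alone was kept.

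The third comparison set aged Hap-I hearts without the diet against the younger western-diet hearts (n = 4 and 4), so age and, by the sample labels, diet differed together. Pdk4 fell 5.97-fold in the aged hearts, from 208.5 ± 36.5 to 33.9 ± 4.98 scaled TPM (log2 fold change -2.58 ± 0.28, limma adjusted p = 0.000168), Angptl4 fell 4.13-fold, from 11.3 ± 5.07 to 1.84 ± 0.82 (log2 fold change -2.05 ± 0.28, adjusted p = 0.00218), and Ucp3 fell 3.59-fold, from 38.5 ± 10.1 to 9.78 ± 1.09 (log2 fold change -1.84 ± 0.27, adjusted p = 0.00347). Clock genes moved in opposite ways: Arntl, the activator that drives the clock, fell by 1.31 ± 0.18 (adjusted p = 0.00218) and its relative Npas2 by 0.64 (adjusted p = 0.0181), while Dbp, Ciart, Hlf and Nr1d1 rose by 1.29, 1.02, 0.94 and 0.71 (adjusted p = 0.0118, 0.0158, 0.00364 and 0.0263). C7 rose 3.55-fold (adjusted p = 0.0153), Tusc3, a subunit of the oligosaccharyltransferase, 4.05-fold (adjusted p = 0.0419) and Abat, the GABA transaminase, 2.14-fold (adjusted p = 0.0175). Gnb3, a G protein beta subunit, rose by 1.00 (adjusted p = 0.00341) and Hcn4, a pacemaker channel, by 0.46 (adjusted p = 0.0427). Cldn5, an endothelial tight junction protein, fell by 0.95 (adjusted p = 0.0162) and Gchfr by 1.04 (adjusted p = 0.0446). Myh6 rose by 1.34 (adjusted p = 0.0469), with 32.5% of its words shared with other genes. Ahcy (1.48), mt-Nd3 (-2.16), mt-Co3 (-1.36) and Eif3j2 (-1.0) passed at adjusted p = 0.0248, 1.08e-05, 0.0369 and 0.00188 and are uncertain, since 79.4% to 99.9% of their words lie in other genes as well. Angptl4 lies on chromosome 17 at 33773750 to 33781830 in GRCm38.

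Of the 11 genes in the negative arm and outputs of the clock, 8 rose, 0 fell and all 11 rose adjusted over the list alone (median 0.71, camera adjusted p = 3.5e-11; adjusted p = 0.064 with an estimated correlation). Of 5 positive arm genes, 2 fell and 3 fell adjusted over the list alone (median -0.38, adjusted p = 0.00386; adjusted p = 0.183 with an estimated correlation). Of 35 genes of fatty acid oxidation and PPARalpha targets, 4 fell and 12 fell adjusted over the list alone (adjusted p = 9.77e-06; adjusted p = 0.627 with an estimated correlation). The median of -0.19 turned to 0.16 without scaling and to 0.02 with mitochondrial transcripts left out of the scaling, where the test, which compares the list with other genes, still called it lower. Of 13 mitochondrially encoded transcripts, 2 fell and 4 fell adjusted over the list alone (median -0.37, adjusted p = 0.000942; adjusted p = 0.627 with an estimated correlation), and quantile normalization turned the median to 0.04; without younger replicate 2 it was -0.18. Of 12 pericyte and smooth muscle markers, 1 rose and 6 rose adjusted over the list alone (median 0.41, adjusted p = 0.00308; adjusted p = 0.289 with an estimated correlation). The 33 fibrosis genes had 0 called members over all genes or adjusted over the list alone and a median of 0.28 (adjusted p = 0.0184; adjusted p = 0.777 with an estimated correlation), a call lost without aged replicate 3 (median 0.15, adjusted p = 0.0582) or younger replicate 2 or 3 (0.156 and 0.0516). It was also lost without scaling (median 0.52, adjusted p = 0.399), with mitochondrial transcripts left out of the scaling (median 0.50, adjusted p = 0.153), with a sex covariate (0.0897; 0.185 with the length correction as well) and among the libraries with Y-linked transcripts (0.066). All 47 ribosomal protein genes had negative values, with 0 called over all genes or adjusted over the list alone and a median of -0.24 (adjusted p = 9.28e-06; adjusted p = 0.718 with an estimated correlation), which was 0.11 without scaling, -0.08 after the length correction or without younger replicate 2, and -0.41 without younger replicate 4. Its call was lost among the libraries with Y-linked transcripts (median -0.04, adjusted p = 0.235) and with length and sex corrected together (median -0.03, adjusted p = 0.29). Rps25, Rpsa and Rpl5 of this list were at -0.42, -0.49 and -0.46, did not pass, and share 45.9% to 94.8% of their words with other genes. The interferon list had a median of -0.57 with 0 called either way or adjusted over the list alone (adjusted p = 0.00136; adjusted p = 0.749 with an estimated correlation). Agtr1a (0.40, adjusted p = 0.116), Ace (0.88, adjusted p = 0.155), Myh7 (1.06, adjusted p = 0.16), Nppb (0.93), Nppa (1.00), Agt (0.02), Col1a1 (0.56) and Col3a1 (0.38) did not pass.

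In all, 244 genes passed, 143 higher and 101 lower in the aged hearts, 29 by 2-fold or more, with 2459 at an unadjusted p under 0.05. The split was 149 higher and 13 lower without scaling and 59 and 18 with mitochondrial transcripts left out. The rank correlation of fold change with transcript length was 0.51, and 167 genes passed after the length correction. The count was 92, 133, 52 and 38 without aged replicates 1, 2, 3 and 4, 59, 75 and 89 without younger replicates 1, 2 and 3, and 737 without younger replicate 4. Pdk4, Angptl4, Ucp3, Dbp, Hlf, Arntl, Gnb3, mt-Nd3 and Eif3j2 passed without any 1 library; the other 12 reached an adjusted p of 0.0567 or more without some library. With a sex covariate 78 genes passed, without Tusc3, Myh6, Abat, Cldn5, Gchfr, mt-Co3 and Hcn4. Among the libraries with Y-linked transcripts 12 passed, and of the 21 named genes that had passed Pdk4, Dbp, Gnb3, Nr1d1 and mt-Nd3 were kept and the others were lost, Angptl4, Ucp3, Hlf, Arntl and Eif3j2 among them.

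**Figure D3:**
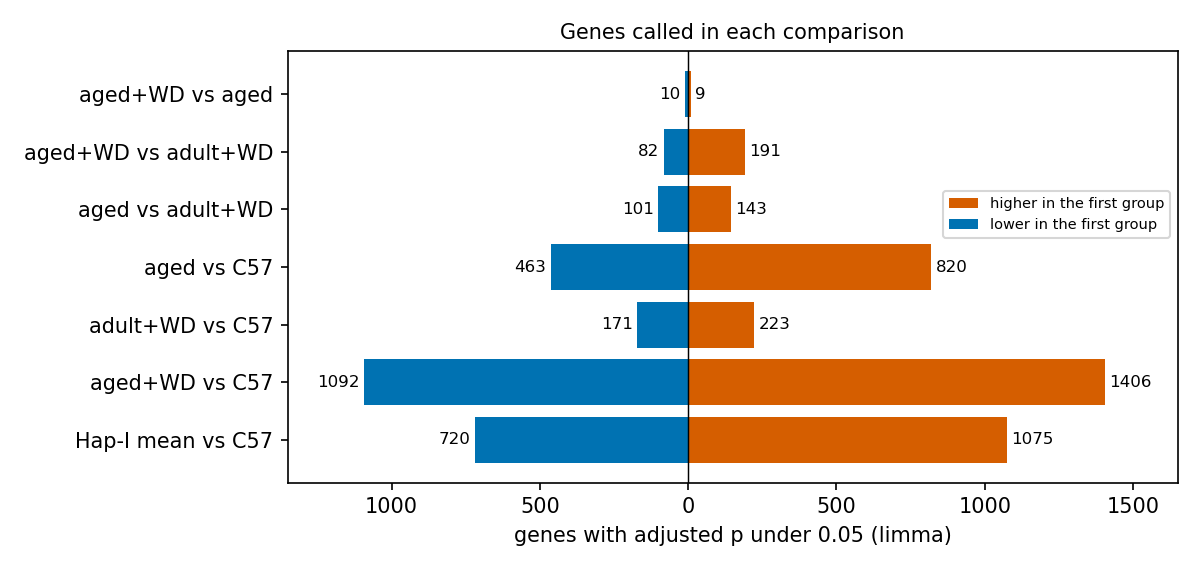
Genes called by limma at an adjusted p under 0.05 in each of the 7 comparisons, as bars from 0 for genes higher and genes lower in the first-named group. Counts ran from 19 for aged Hap-I hearts with against without western diet to 2498 for aged western-diet Hap-I against C57 hearts.

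Against adult C57 hearts (n = 3), the aged Hap-I hearts without the diet (n = 4) differ by transgene and age together. Agtr1a, the mouse receptor gene of angiotensin II, rose 1.49-fold, from 11.1 ± 2.31 to 16.9 ± 1.76 scaled TPM (log2 fold change 0.58 ± 0.15, limma adjusted p = 0.0214). The call was lost without C57 replicate 1 or 3 or aged replicate 4 (up to 0.118). Whether reads of the human transgene add to Agtr1a was not tested. Kcnd3, a channel of the transient outward potassium current, rose by 0.60 on the log2 scale (adjusted p = 0.00535). Arhgap5, a GTPase activator, Clasp1, a microtubule plus-end protein, and Tfrc, the transferrin receptor, rose 3.59-, 3.49- and 3.36-fold (adjusted p = 0.00115, 0.00443 and 0.0126), and Tusc3 rose 3.92-fold (adjusted p = 0.0244). The glucocorticoid target Tsc22d3 fell 2.27-fold, from 70.2 ± 13 to 30.2 ± 3.24 (log2 fold change -1.18 ± 0.23, adjusted p = 0.00632), Sult1a1 fell 1.85-fold (adjusted p = 0.0112), and Mt2, a metallothionein, 2.54-fold (adjusted p = 0.0468). Scgb1a1, a secretoglobin of airway cells, fell by 2.62 (adjusted p = 0.0201), with 24.1, 1.48 and 3.02 scaled TPM in the 3 C57 hearts, and was lost without C57 replicate 1 or aged replicate 4 (up to 0.0899). Plac9a (1.88, adjusted p = 0.0418), Dynlt1b (-1.48, adjusted p = 0.0104) and Tgtp1 (-1.42, adjusted p = 0.0384) share 86.9% to 99.6% of their words with other genes and are uncertain. Agtr1a lies on chromosome 13 at 30336441 to 30382867 in GRCm38.

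Of 51 nuclear genes of oxidative phosphorylation, 0 rose, 5 fell and 5 fell adjusted over the list alone (median -0.31, camera adjusted p = 7.97e-07; adjusted p = 0.637 with an estimated correlation). Ndufa9 of complex I fell by 0.74 (adjusted p = 0.00973), Atp5b of the ATP synthase fell 1.48-fold (adjusted p = 0.0116) and Cox5b 1.51-fold (adjusted p = 0.0343), with 32.7% of the words of Cox5b shared with other genes and its level uncertain. The list's median was -0.11 after the length correction, and quantile normalization ended its call (0.293). Of 14 glucocorticoid targets, 6 fell and 10 fell adjusted over the list alone (median -0.68, adjusted p = 6.96e-06; adjusted p = 0.487 with an estimated correlation). Of 22 genes of the unfolded protein response, 6 fell and 8 fell adjusted over the list alone (median -0.35, and -0.54 without C57 replicate 2; adjusted p = 0.000249; adjusted p = 0.487 with an estimated correlation). Of 28 genes of calcium handling and ion channels, 7 rose, 0 fell and 8 rose adjusted over the list alone (median 0.28, adjusted p = 0.00116; adjusted p = 0.487 with an estimated correlation). Of 26 adrenergic and hypertrophic genes, 4 rose and 1 fell, with the same counts adjusted over the list alone (median 0.21, adjusted p = 0.0102; adjusted p = 0.487 with an estimated correlation), a call lost after the length correction (0.0686). All 26 interferon genes had negative values, and 1 fell, also 1 adjusted over the list alone (median -0.50, and -0.30 without C57 replicate 3; adjusted p = 0.00136; adjusted p = 0.76 with an estimated correlation). Markers of fibroblasts moved beside them, with 3 of 15 fallen and 4 adjusted over the list alone (median -0.40, adjusted p = 0.00284; adjusted p = 0.637 with an estimated correlation). So did 16 endothelial markers, 4 fallen and also 4 adjusted over the list alone (median -0.22, adjusted p = 0.012; adjusted p = 0.637 with an estimated correlation), a call lost without C57 replicate 3 (0.0671) and under quantile normalization (0.0685). Of 10 white adipocyte markers 2 fell, also 2 adjusted over the list alone (median -0.41, adjusted p = 0.0491; adjusted p = 0.487 with an estimated correlation). Their call was lost without C57 replicate 1 (median -0.18, adjusted p = 0.177) or aged replicate 1, 2 or 4 (up to 0.127), and with the atrial covariate (median -0.16, adjusted p = 0.159), under quantile normalization (0.101), after the length correction (0.0954; 0.088 with sex as well), among the libraries with Y-linked transcripts (0.065) and without the 2 libraries that stood apart (0.0589). Without aged replicates 2 and 3 the median was -0.26 and -0.69. Agt, Ace (-0.09), Nppa (-1.80, adjusted p = 0.351), Nppb (1.12, adjusted p = 0.205), Myh7 (0.62), Col1a1 and Col3a1 did not pass.

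In this comparison 1283 genes passed, 820 higher and 463 lower in the aged Hap-I hearts, 109 by 2-fold or more, with 3180 at an unadjusted p under 0.05. The split was 204 and 21 without scaling and 320 and 56 with mitochondrial transcripts left out, and the rank correlation of fold change with length was 0.48. The count was 392 and 372 without C57 replicates 1 and 3, and 827, 663 and 558 without aged replicates 1, 3 and 4. Arhgap5, Clasp1, Ndufa9, Tsc22d3, Sult1a1 and Kcnd3 passed without any 1 library; Atp5b was lost without C57 replicate 3 (0.0557), and the other 9 reached 0.05 to 0.211. Without scaling, Kcnd3, Tsc22d3, Sult1a1, Atp5b, Ndufa9, Plac9a, Tgtp1 and Mt2 did not pass. With the atrial covariate, Plac9a, Scgb1a1, Tgtp1, Mt2 and Agtr1a did not.

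The younger western-diet Hap-I hearts against C57 hearts (n = 4 and 3) differ by transgene and, by their sample labels, diet. Clock genes changed in both directions. Hlf fell 2.94-fold, from 7.8 ± 1.69 to 1.99 ± 0.53 scaled TPM (log2 fold change -1.56 ± 0.15, limma adjusted p = 8.4e-05), Dbp 4.15-fold, from 14.9 ± 2.64 to 2.92 ± 1.08 (log2 fold change -2.05 ± 0.24, adjusted p = 0.000282), Ciart 3.41-fold and Per2 2.38-fold (adjusted p = 0.000282 and 0.000677). Arntl rose 3.9-fold, from 0.42 ± 0.25 to 4.57 ± 1.14 (log2 fold change 1.97 ± 0.19, adjusted p = 8.74e-05), and Npas2 1.79-fold (adjusted p = 0.00395). Pdk4 rose 3.03-fold, from 72.7 ± 36.9 to 208.5 ± 36.5 (adjusted p = 0.0104), Slc41a3, a magnesium transporter, 2.7-fold (adjusted p = 0.000208), Sh3glb1 2.72-fold (adjusted p = 0.0184), and Fos and Tfrc 2.97-fold each (adjusted p = 0.0378 and 0.0388). Timp3 and Timp4, inhibitors of matrix metalloproteinases, fell 3.17- and 3.01-fold (adjusted p = 0.00287 for both), with 36.4% of the words of Timp3 shared with its overlapping neighbour Syn3. Casq1, the calsequestrin of skeletal muscle, fell 3.99-fold (adjusted p = 0.0143). Of 3 skeletal muscle markers 1 fell, also 1 adjusted over the list alone (median -0.70, adjusted p = 0.0485; adjusted p = 0.334 with an estimated correlation), a call lost without C57 replicate 1 or 2 (0.159 and 0.0515) or younger replicate 3 or 4 (0.0608 and 0.114), after the length correction (0.149; 0.0628 with sex as well), without the 2 libraries that stood apart (0.125) and with the atrial covariate (0.0552). Hlf lies on chromosome 11 at 90336536 to 90390895 and Timp4 on chromosome 6 at 115241892 to 115252205 in GRCm38.

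Of 11 genes in the negative arm and outputs of the clock, 9 fell, 0 rose and all 11 fell adjusted over the list alone, at a median of -1.17 (camera adjusted p = 5.82e-16; adjusted p = 0.016 with an estimated correlation). No other list call in any comparison held with an estimated correlation. Of 5 genes of the positive arm list, which includes the repressors Nfil3 and Cry1, 3 rose and 0 fell. Adjusted over the list alone 4 rose and 1 fell (median 0.84, camera adjusted p = 0.000814, and 0.0858 with an estimated correlation). Of 22 genes of the unfolded protein response, 5 fell and 16 fell adjusted over the list alone (median -0.62, adjusted p = 6.02e-08; adjusted p = 0.221 with an estimated correlation). Of these, the chaperone Calr fell 1.76-fold, Herpud1 2.01-fold, Creld2 1.66-fold and Manf 1.63-fold (adjusted p = 0.0405, 0.0184, 0.0134 and 0.04). Of 33 fibrosis genes, 3 fell and 10 fell adjusted over the list alone (median -0.51, adjusted p = 6.44e-06; adjusted p = 0.572 with an estimated correlation), among them the collagen-binding Fmod (-1.26, adjusted p = 0.0149) and the matricellular Ccn2 (-1.21, adjusted p = 0.0464). Of 51 nuclear genes of oxidative phosphorylation, 3 fell and 4 fell adjusted over the list alone (median -0.18, adjusted p = 9.38e-05; adjusted p = 0.572 with an estimated correlation), a call that quantile normalization ended (0.204); without younger replicate 4 the median was -0.08. Of 35 genes of fatty acid oxidation and PPARalpha targets, 3 rose and 4 rose adjusted over the list alone (adjusted p = 0.00644; adjusted p = 0.572 with an estimated correlation), with a median of 0.14 that was -0.04 without scaling. The call was lost without C57 replicate 3 (median 0.03, adjusted p = 0.166), and the median was 0.29, 0.24, 0.09 and 0.21 without C57 replicate 2 and younger replicates 2, 3 and 4. Endocardial and large-vessel markers (8 tested, 0 called, 3 fallen adjusted over the list alone) moved beside the fibrosis genes at a median of -0.68 (adjusted p = 0.00022; adjusted p = 0.268 with an estimated correlation). Of 15 fibroblast markers, 0 were called and 3 fell adjusted over the list alone (median -0.30, adjusted p = 0.0063; adjusted p = 0.572 with an estimated correlation), a call lost with the atrial covariate (0.0552). Of 12 pericyte and smooth muscle markers, 2 fell, also 2 adjusted over the list alone (median -0.40, adjusted p = 0.0052; adjusted p = 0.268 with an estimated correlation). Of 3 mesothelial markers, 1 fell and 2 fell adjusted over the list alone (median -1.01, adjusted p = 0.0389; adjusted p = 0.457 with an estimated correlation), a call lost without C57 replicate 1 (median -0.62, adjusted p = 0.0984) or younger replicate 3 (0.0666), with the atrial covariate (0.071), after the length correction (0.0666; 0.0595 with sex as well) and without the 2 libraries that stood apart (0.0564). Of 16 endothelial markers, 1 rose and 1 fell, and 1 rose and 5 fell adjusted over the list alone (median -0.46, adjusted p = 0.0102; adjusted p = 0.572 with an estimated correlation), a call lost without C57 replicate 3 (0.0867) and with a sex covariate (0.0645). The 10 white adipocyte markers had 0 called over all genes or adjusted over the list alone (median -0.63, adjusted p = 0.0104; adjusted p = 0.268 with an estimated correlation), a call lost without C57 replicate 1 (median -0.27, adjusted p = 0.0616) and with the atrial covariate (0.0552). The 9 atrial markers, with 0 called over all genes or adjusted over the list alone, were at a median of -2.54 (adjusted p = 0.00755; adjusted p = 0.572 with an estimated correlation), a call lost without C57 replicate 1 (0.0616) or 3 (0.0867); without C57 replicate 2 the median was -4.17. Agtr1a was at 0.17 ± 0.15 (adjusted p = 0.535), Ace at -0.97 (adjusted p = 0.143) and Nppa at -2.80 (adjusted p = 0.204); Agt, Nppb, Myh7, Col1a1 and Col3a1 did not pass.

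Here 394 genes passed, 223 higher and 171 lower in the Hap-I hearts, 73 by 2-fold or more, with 2330 at an unadjusted p under 0.05. The split was 24 and 94 without scaling and 47 and 77 with mitochondrial transcripts left out. The count was 78 and 105 without C57 replicates 1 and 3, and 181 and 178 without younger replicates 2 and 3. Slc41a3, Dbp, Ciart, Timp3, Timp4, Hlf, Per2, Arntl and Npas2 passed without any 1 library; Pdk4, Casq1, Sh3glb1, Creld2 and Fmod were lost without C57 replicate 1 or 3 (adjusted p up to 0.0674, 0.0738, 0.0962, 0.0756 and 0.0855), and the other 6 reached up to 0.207 without some library. With a sex covariate 139 genes passed, without Fos, Tfrc, Sh3glb1, Fmod, Ccn2, Herpud1, Manf and Calr. Among the libraries with Y-linked transcripts 69 passed, without Pdk4, Fos, Sh3glb1, Timp4, Creld2, Herpud1, Manf, Calr, Ccn2 and Npas2. With the atrial covariate 100 passed, without Fos, Tfrc, Sh3glb1, Casq1, Creld2, Herpud1, Manf, Calr and Ccn2.

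The aged western-diet Hap-I hearts against C57 hearts (n = 5 and 3) differ by transgene, age and diet at once. Hipk2, a stress-responsive kinase, rose 4.9-fold, from 1.22 ± 0.29 to 10.4 ± 3.43 scaled TPM (log2 fold change 2.29 ± 0.31, limma adjusted p = 0.000337), and Xirp2, an actin-binding protein of intercalated discs, rose 3.45-fold, from 13.6 ± 3.03 to 49.9 ± 11.5 (log2 fold change 1.79 ± 0.21, adjusted p = 0.000177). Arhgap5, Clip4 and Clasp1 rose 4.01-, 3.45- and 3.3-fold (adjusted p = 0.000201, 0.00294 and 0.00177). Of respiratory chain genes, Atp5b fell 1.85-fold, from 5361 ± 134 to 2896 ± 166 (log2 fold change -0.89 ± 0.12, adjusted p = 0.000328), and Ndufv1 and Ndufa9 1.53- and 1.72-fold (adjusted p = 0.00146 and 0.00249). Atrial genes called lower were Myl7 at -7.10, Myl4 at -5.78, Sln at -5.18, Mybphl at -4.21 and Sbk3 at -2.94 (adjusted p = 0.0303, 0.0342, 0.0385, 0.039 and 0.0123). These 5 calls were lost on leaving out C57 replicate 1, and the first 4 also without C57 replicate 3 or without aged western-diet replicate 1, 2 or 3. Sln and Mybphl were also lost without aged western-diet replicate 5. All 5 were lost with the atrial covariate, but it is built from the first 4, so for these 4 that loss was fixed in advance. Their adjusted p reached up to 0.185 with 1 library left out. Xirp2 lies on chromosome 2 at 67446002 to 67526614, Hipk2 on chromosome 6 at 38694390 to 38876165, Atp5b on chromosome 10 at 128083273 to 128090391 and Myl7 on chromosome 11 at 5896637 to 5898782 in GRCm38.

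Of 51 nuclear genes of oxidative phosphorylation, 19 fell, 0 rose and 25 fell adjusted over the list alone, at a median of -0.41 (camera adjusted p = 4.76e-10; adjusted p = 0.554 with an estimated correlation). The median was -0.25 after the length correction and -0.11 under quantile normalization. Of 17 genes of the tricarboxylic acid cycle, 6 fell, and 1 rose and 6 fell adjusted over the list alone (median -0.25, adjusted p = 0.00491; adjusted p = 0.592 with an estimated correlation), a call lost without C57 replicate 2 (0.0531) or under quantile normalization (0.645). Of 22 genes of the unfolded protein response, 10 fell and 12 fell adjusted over the list alone (median -0.50, adjusted p = 5.97e-05; adjusted p = 0.554 with an estimated correlation), among them Calr (-1.03, adjusted p = 0.00256) and Creld2 (-0.75, adjusted p = 0.00213). Of 33 fibrosis genes, 7 fell and 9 fell adjusted over the list alone (median -0.49, adjusted p = 0.00388; adjusted p = 0.671 with an estimated correlation), with Fmod at -1.39 and the cartilage oligomeric matrix protein Comp at -1.57 (adjusted p = 0.00158 and 0.00533). The list's call was lost without C57 replicate 3 (median -0.33, adjusted p = 0.0517) and with the atrial covariate (median -0.25, adjusted p = 0.219), and without aged western-diet replicate 2 the median was -0.27. Of 15 fibroblast markers, 4 fell and 7 fell adjusted over the list alone (median -0.54, adjusted p = 0.0132; adjusted p = 0.618 with an estimated correlation). Their call was lost without aged western-diet replicate 4 (0.0568), under quantile normalization (0.0875) and with the atrial covariate (0.165). Of 16 endothelial markers 3 fell and of 10 white adipocyte markers 2, the same counts as adjusted over the list alone (medians -0.38 and -0.63, adjusted p = 0.0315 for both; adjusted p = 0.592 and 0.554 with an estimated correlation). The endothelial call was lost without C57 replicate 3 (0.107) or aged western-diet replicate 2 or 3 (0.0707 and 0.052), and the adipocyte call without C57 replicate 1 (median -0.33, adjusted p = 0.0798) or aged western-diet replicate 5 (0.0502). Both were lost with the atrial covariate (0.0605 and 0.227) and under quantile normalization (0.165 and 0.0965). The endothelial call was also lost with a sex covariate (median -0.22, adjusted p = 0.128), with length and sex corrected together (0.153) and among the libraries with Y-linked transcripts (0.165). Of 11 genes in the negative arm and outputs of the clock, 5 fell and 5 fell adjusted over the list alone (median -0.38, adjusted p = 0.00388; adjusted p = 0.554 with an estimated correlation). Of 9 atrial markers, 4 fell and 5 fell adjusted over the list alone (median -3.16, adjusted p = 0.00771; adjusted p = 0.592 with an estimated correlation). Of 8 endocardial and large-vessel markers, 4 fell and 5 fell adjusted over the list alone (median -0.69, adjusted p = 0.0171; adjusted p = 0.554 with an estimated correlation), a call lost with the atrial covariate (0.131). Agt, the angiotensin precursor gene, fell by 0.46 (adjusted p = 0.0372) from 1.04 ± 0.32, a call lost without C57 replicate 1 or 3 or western-diet replicate 1, 2 or 3 (up to 0.176). Agtr1a was at 0.21 ± 0.14 (adjusted p = 0.303), Ace at -0.89 (adjusted p = 0.0786), Nppa at -3.16 (adjusted p = 0.0615), Col3a1 at -1.19 (adjusted p = 0.0572) and Col1a1 at -0.91 (adjusted p = 0.123), and Nppb and Myh7 did not pass.

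In all, 2498 genes passed, 1406 higher and 1092 lower, 219 by 2-fold or more, with 4050 at an unadjusted p under 0.05. The split was 282 and 332 without scaling and 679 and 324 with mitochondrial transcripts left out. The rank correlation of fold change with length was 0.34. The count was 1372 and 1257 without C57 replicates 1 and 3. With a sex covariate 1392 genes passed, without Myl7, Myl4, Sln, Mybphl and Agt. With the atrial covariate 667 passed, without Clip4, Comp, Agt and the 5 atrial genes.

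Averaged over the 3 Hap-I groups (n = 13) and set against C57 (n = 3), the comparison gives an equal-weight average difference, which 1 or 2 of the groups can carry, with transgene inseparable from age and diet. Arhgap5 rose 3.4-fold (log2 fold change 1.77 ± 0.21, limma adjusted p = 0.000264), Hipk2 3.15-fold (adjusted p = 0.00168), Clasp1 2.94-fold (adjusted p = 0.00215), Nt5c1a, a cytosolic AMP nucleotidase, 2.57-fold (adjusted p = 0.00136) and Xirp2 2.55-fold (adjusted p = 0.000654). Scn4b, a sodium channel beta subunit, rose 2.22-fold (log2 fold change 1.15 ± 0.14, adjusted p = 0.000339) and Kcnd3 1.48-fold (adjusted p = 0.00176). Among clock genes Arntl and Clock rose 2.39- and 2.22-fold (adjusted p = 0.00044 and 0.00145), and Hlf, Ciart, Dbp and Tef fell by 1.07, 1.22, 1.21 and 0.70 on the log2 scale (adjusted p = 0.000235, 0.000979, 0.00189 and 0.00269). Casq1, Timp4, Comp and Fmod fell 3.09-, 2.3-, 2.44- and 2.28-fold (adjusted p = 0.00537, 0.00201, 0.0102 and 0.00259). Atp5b, Ndufa9 and Ndufv1 fell by 0.66, 0.73 and 0.40 (adjusted p = 0.00145, 0.00247 and 0.00961). Agtr1a was at 0.32 ± 0.12 (adjusted p = 0.0872) and Nppa at -2.58 (adjusted p = 0.0937); Agt, Ace, Nppb, Myh7, Col1a1 and Col3a1 did not pass.

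Of 51 nuclear genes of oxidative phosphorylation, 13 fell, 0 rose and 16 fell adjusted over the list alone (median -0.28, camera adjusted p = 1.89e-08; adjusted p = 0.466 with an estimated correlation). The median was -0.18 after the length correction, and quantile normalization ended the call (0.092). Of 22 genes of the unfolded protein response, 13 fell and 14 fell adjusted over the list alone (median -0.50, adjusted p = 1.61e-06; adjusted p = 0.466 with an estimated correlation). Of 11 genes in the negative arm and outputs of the clock, 7 fell and 9 fell adjusted over the list alone (median -0.70, adjusted p = 1.61e-06; adjusted p = 0.417 with an estimated correlation). Of 33 fibrosis genes, 6 fell and 6 fell adjusted over the list alone (median -0.36, and -0.20 without C57 replicate 3; adjusted p = 0.00105; adjusted p = 0.621 with an estimated correlation). Of 28 calcium handling and ion channel genes, 5 rose and 7 rose adjusted over the list alone (median 0.20, adjusted p = 0.0143; adjusted p = 0.466 with an estimated correlation), a call lost after the length correction (0.0731). Beside these, the 9 atrial markers had 0 called over all genes or adjusted over the list alone and a median of -2.58 (adjusted p = 0.0103; adjusted p = 0.556 with an estimated correlation), lost without C57 replicate 1 (0.0537) or 3 (0.0888); without C57 replicate 2 the median was -3.95. The fibrosis and atrial lists were not called for aged hearts without the diet (medians -0.21 and -1.80, adjusted p = 0.0562 and 0.115), nor was the calcium list in younger or aged western-diet hearts (adjusted p = 0.0961 and 0.125). The clock's negative arm was at -1.17 in younger western-diet hearts and at -0.41 and -0.38 in aged hearts without and with the diet, with the hour of collection unknown. Of 15 fibroblast markers 4 fell, 7 adjusted over the list alone (median -0.45, adjusted p = 0.00322; adjusted p = 0.506 with an estimated correlation). Of 8 endocardial and large-vessel markers 3 fell, 4 adjusted over the list alone (median -0.54, adjusted p = 0.00462), of 16 endothelial markers 5 and 6 (median -0.37, adjusted p = 0.0103), and of 10 white adipocyte markers 2 and 2 (median -0.50, adjusted p = 0.0116), each at an adjusted p of 0.466 with an estimated correlation. The endothelial call was lost without C57 replicate 3 (0.0676), and the adipocyte call without C57 replicate 1 (median -0.28, adjusted p = 0.0537) and with the atrial covariate (0.0922).

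In this comparison 1795 genes passed, 1075 higher and 720 lower, 106 by 2-fold or more, with 3577 at an unadjusted p under 0.05. Without scaling the split was 178 and 205. The count was 576 and 563 without C57 replicates 1 and 3. Of the 20 named genes that passed, 18 did so without any 1 library, and Ndufv1 and Comp were lost without C57 replicate 1 or 3 (adjusted p up to 0.0547 and 0.0987). Without scaling Ndufv1, Tef and Kcnd3 were lost, and with the atrial covariate Casq1 and Comp. The comparisons against C57 share the same 3 control hearts, so their results are not independent of each other.

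**Figure D4:**
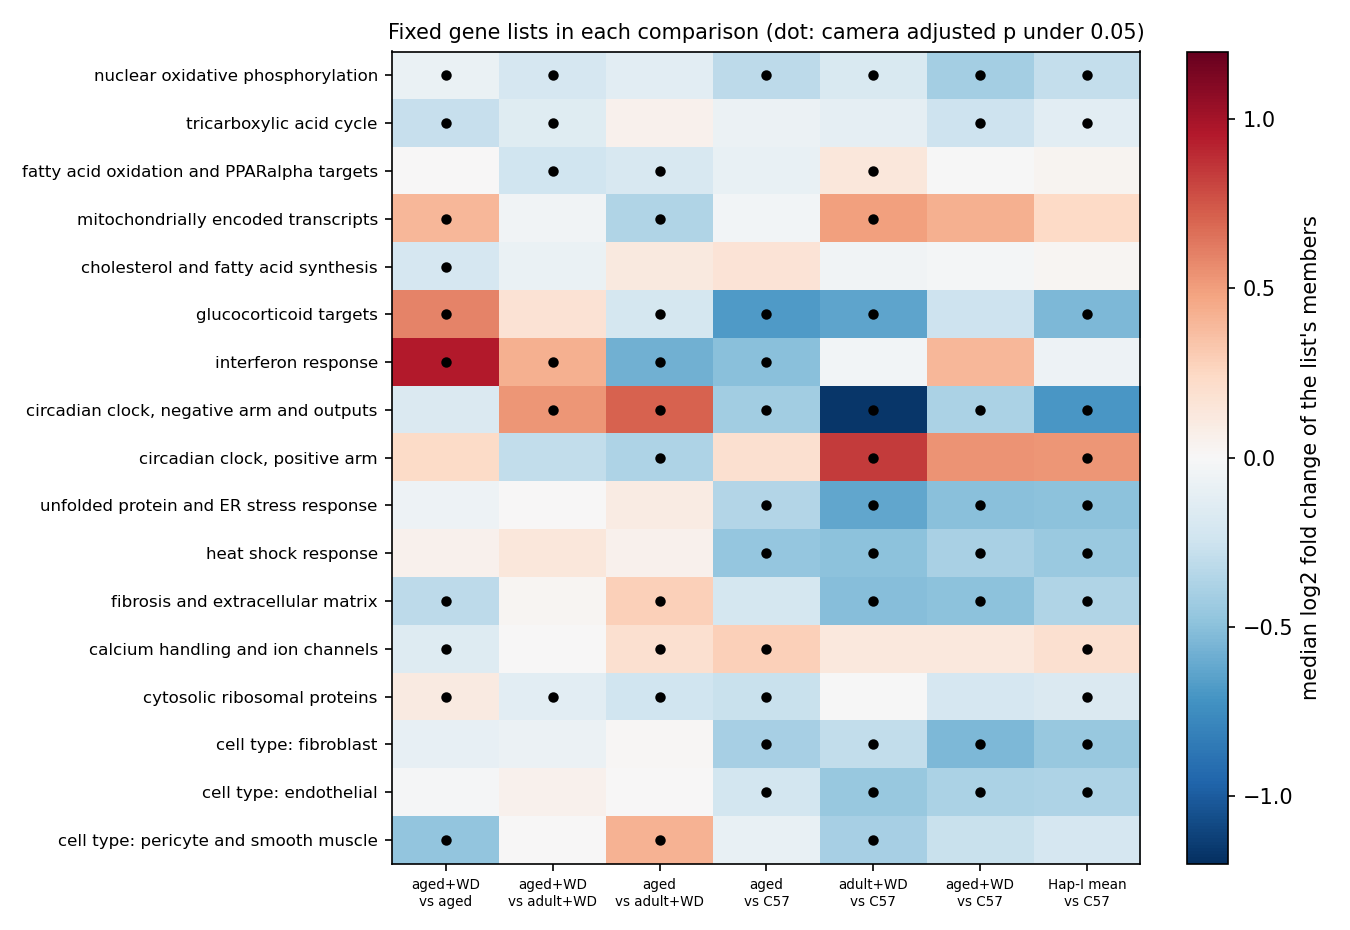
Median log2 fold change of the tested members of 17 gene lists in each of the 7 comparisons, as colours on a symmetric scale; a dot marks a camera adjusted p under 0.05 at the preset correlation. The negative arm and outputs of the clock stand at -1.17 in younger western-diet Hap-I against C57 hearts and at 0.71 in aged Hap-I hearts without the diet against younger western-diet ones, while the fatty acid oxidation median of -0.19 in that last comparison is 0.16 without scaling.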

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

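The tests of age, of atrial content and of the Ahcy reads were chosen only after the results were seen; the length correction was chosen after the data were seen but before its effect on the calls was known, and the splits of the samples were fixed beforehand. Among 223 pairs of a named gene and a group of 4 or 5 libraries, 17 had 1 library set apart, by a gap to its nearest neighbour that was large against the group's range. Chance sets apart about 1 in 20 groups, here 11.2. Of the 17, 6 lay in aged western-diet replicate 5. With the gap as a share of the range, these were Arhgap5 (0.849; 3.96 scaled TPM against 6.2 to 6.69 in the other 4), Casq1 (0.726; 5.06 against 1.24 to 1.94), Ciart (0.717; 3.31 against 4.2 to 4.6), Clip4 (0.942; 8.95 against 18.9 to 19.7), Hipk2 (0.72; 4.63 against 9.76 to 12.8) and Nt5c1a (0.84; 4.01 against 7.82 to 8.82). Aged western-diet replicate 4 was apart in the atrial genes Myl4 (0.795; 11.1 against 1.83 to 2.81), Myl7 (0.844; 17.6 against 0.36 to 1.04) and Sln (0.953; 2.16 against 0 to 0.055), and replicate 3 in Kcnd3 (0.826; 2.61 against 2.01 to 2.11). In aged hearts without the diet, Scgb1a1 was 0.11 in replicate 1 and listed at 0 in the others (share 1). Rpl5 (0.857; 7.86 against 5.64 to 5.92) and Rpsa (0.856; 11.4 against 9.63 to 9.87) were apart in replicate 2. In younger western-diet hearts the libraries apart were replicate 1 in Nt5c1a (0.865; 2.72 against 4.45 to 4.78), replicate 2 in Sh3glb1 (0.889; 8.96 against 4.11 to 4.5), replicate 3 in Ahcy (0.89; 0.53 against 4.24 to 5.11) and replicate 4 in Abat (0.834; 6.68 against 2.34 to 2.83).

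Chance was tested by splitting the same libraries in other ways. In each comparison of 2 groups the real split had a share under 0.05, but in the first 2 other splits called more genes, so chance stays open there. For aged hearts with against without the diet, 2 of 100 splits called at least the 19 genes of the real one, and the highest other (western-diet replicates 1 to 4 against the rest) called 46. For aged against younger hearts, both on the western diet, 3 of 100 splits reached 273, and the highest others called 2186 and 835. These splits set aged replicates 2 and 4 with younger replicates 2 and 3, or 1 and 2, against the rest, and they point to a structure of the samples other than the groups. For aged hearts without the diet against younger western-diet hearts, 1 of 35 splits, the real one, reached its count (244; highest other 1). The same held against C57 for aged Hap-I (1 of 35, 1283 against 53) and younger western-diet Hap-I (1 of 35, 394 against 115). It also held for aged western-diet Hap-I (1 of 56, 2498 against 998). For the Hap-I mean it was 1 of 100 (1795 against 1588), but its other splits also regrouped the Hap-I hearts, so chance stays open. The split calling 998 set apart aged western-diet replicates 1, 3 and 5, and that with 1588 their replicates 2 and 4 and younger replicate 2.

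Long transcripts were higher in libraries of aged mice. Still called after the length correction, in the same direction, were 52.5% of 244 genes for aged hearts without the diet against younger western-diet hearts. Against C57 it was 52.6% of 1283 for aged and 69.9% of 2498 for aged western-diet hearts. This argues against the length trend as the whole cause there. For aged against younger hearts, both on the western diet, 42.1% of 273 passed. It stays open there, since without scaling only 19 did. The trend averaged 0.23 in 9 libraries of aged and -0.26 in 7 of adult mice (exact permutation test, two-sided, p = 0.00769), with overlapping ranges. Age and a difference in how the libraries were prepared cannot be told apart here, since the labels give no batch and no measure of RNA integrity.

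Atrial markers were lower in aged western-diet than in C57 hearts. Within groups, 5 other atrial markers followed Myl7 from library to library with a median correlation of 0.85 (0.56 to 0.99), which is consistent with different amounts of atrial tissue in the samples. A change of atrial gene expression with genotype, age and diet stays open and cannot be told apart: the lowest C57 library held 1.53 times the Myl7 of the highest aged western-diet library (26.8 against 17.6 scaled TPM), while C57 libraries alone spanned 68.7-fold.

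Ahcy, an enzyme of the methionine cycle, was at 3.67 ± 2.12 scaled TPM in the 4 younger western-diet hearts and at 10.6 ± 0.83 in the other 12, a ratio of 0.347. Its near-identical copy Gm4737 was at 9.15 ± 2.15 in those 4 and listed at 0 in the other 12. Of the 31-base words of Gm4737, 93.2% lie in Ahcy transcripts, and the sum of both genes differed by a ratio of 1.21 (exact permutation test, two-sided, p = 0.000549, the smallest this design allows), so reads divided between the copies may account for the fall of Ahcy. A chromosome segment of another strain around Ahcy stays open: 5 of 53 genes tested in its 5 Mb window were called (exact hypergeometric p = 0.0084, adjusted p = 1 over 530 windows). Age alone as the cause is argued against, since Ahcy in the 3 adult C57 hearts was 1.06 times that in the 9 aged hearts (11 ± 0.47 against 10.4 ± 0.89) and Gm4737 was listed at 0 in both. An effect of age in Hap-I mice only stays open.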

How the results depend on the processing

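The length correction alone or with a sex covariate, the fit of the libraries with Y-linked transcripts, the atrial covariate and the fit without 2 libraries that stood apart were chosen after seeing the data, as was the sex covariate for genes and lists. Precision is limited by 3 to 5 animals a group and by TPM, which keep no depth. No paired analysis was possible because the replicate numbers were given in accession order and the labels pair no samples. A fit of only the groups compared does not apply to the Hap-I mean.

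Counts of called genes follow the order of the report, against 19, 273, 244, 1283, 394, 2498 and 1795. They were 25, 22, 162, 225, 118, 614 and 383 without scaling, 25, 27, 77, 376, 124, 1003 and 618 with mitochondrial transcripts left out of the scaling, and 63, 224, 233, 993, 374, 2164 and 1524 under quantile normalization. Without a filter they were 21, 166, 159, 938, 281, 2181 and 1487, and with at least 5 TPM 6, 172, 137, 924, 329, 1719 and 1281. Library weights gave 316, 1505, 3044, 3609, 2445, 3735 and 3855. A 2-fold threshold left 7, 19, 29, 109, 73, 219 and 106, and an adjusted p under 0.01 left 4, 11, 22, 268, 71, 1002 and 631, since both are stricter. The sex covariate gave 44, 194, 78, 1176, 139, 1392 and 1158, the length correction 110, 156, 167, 868, 658, 2272 and 1684, and both together 64, 114, 70, 763, 204, 1247 and 1058. Libraries with Y-linked transcripts gave 140, 12, 12, 1323, 69, 853 and 1241, the atrial covariate 5, 104, 178, 730, 100, 667 and 563, and the fit without aged western-diet replicate 5 and younger replicate 4 142, 656, 926, 1691, 715, 2973 and 2261. Only the groups compared gave 27, 5, 422, 2428, 68 and 1376. The pseudocounts, the variance trend and the robust variance moved each count by less than 1.5 times. Leaving out 1 library gave 4 to 92, 28 to 572, 38 to 737, 372 to 1182, 78 to 484, 1257 to 2672 and 563 to 2110. Apart from the stricter thresholds, the cause was not tested.

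Over the named genes that passed, 2566 refits kept the direction and the call, 644 kept the direction and lost the call, and 3 turned; of those that had not passed, 50 turned and 90 gained a call. The turned log2 fold changes, with the cause not tested, were these. With the atrial covariate Nppa was 0.42 and Myh7 0.057 for diet in aged hearts, Agtr1a -0.027 and Nppa 1.04 for aged against younger hearts with the diet, Agt -0.002 for aged hearts without the diet against younger ones, Ace 0.016 for aged against C57, and Myl4 0.006, Sln 0.16, Mybphl 0.081 and Nppa 0.29 for aged western-diet against C57. Myl4, Sln and Mybphl belong to that covariate, which brings their values near 0 by construction. Among libraries with Y-linked transcripts Nppb was 0.26 for diet in aged hearts, Ace -0.12, Nppa 0.49, Col1a1 -0.069 and the ribosomal list 0.16 for aged against younger hearts with the diet, Agt -0.059 for aged hearts without the diet against younger ones, and Nppb -0.65 for younger western-diet against C57. For aged against younger hearts with the diet, library weights gave Agtr1a -0.093, Nppa 0.73 and Col1a1 -0.032, the fit without 2 libraries Agtr1a -0.093, Nppa 0.03, Nppb -0.089 and Col1a1 -0.077, the length correction Ace -0.014 and Col1a1 -0.12, and length with sex Col1a1 -0.083. Library weights gave Nppb -0.04 for younger western-diet against C57. Agt for aged hearts without the diet against younger ones was -0.024 with length and sex, -0.12 with sex and -0.07 under quantile normalization. Length with sex gave Myh7 -0.007 for the Hap-I mean. Without scaling Ace was 0.061 for aged against C57, where leaving mitochondrial transcripts out of the scaling gave 0.049. Leaving out 1 library gave Myh7 -0.44 to 0.078 for diet in aged hearts; Agtr1a -0.046 to 0.11, Ace -0.17 to 0.36, Nppa -1.18 to 0.14 and Col1a1 -0.24 to 0.26 for aged against younger hearts with the diet; Agt -0.044 to 0.12 and Nppa -0.014 to 1.63 for aged hearts without the diet against younger ones; Ace -0.20 to 0.027 for aged against C57; and Nppb -0.35 to 0.72 for younger western-diet against C57.

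Of the called lists, 19, 4, 11, 12, 17, 12 and 15 of 20, 6, 13, 16, 19, 15 and 20 kept their call and direction after the length correction, 17, 2, 11, 9, 17, 7 and 14 under quantile normalization, 15, 6, 13, 14, 12, 5 and 17 with the atrial covariate, and 14, 4, 10, 14, 16, 12 and 18 among the libraries with Y-linked transcripts. Under fry, which tests whether a list's genes move one way without comparing them with other genes, 3, 1, 4, 8, 8, 10 and 12 were also called in that direction. The fewest kept without 1 library were 15 and 3 without aged western-diet replicate 5, 10 without aged replicate 3, and 12, 13, 9 and 12 without C57 replicate 3. With an estimated correlation only the clock's negative arm in younger western-diet against C57 hearts was called.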

Other observations

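The genes named in the next paragraph were chosen after their values were seen. The heat shock list was called lower against C57 in all 4 comparisons, with few single genes called. For younger western-diet hearts the median of 16 genes was -0.49, with 0 called over all genes and 8 fallen adjusted over the list alone (camera adjusted p = 0.00022; adjusted p = 0.268 with an estimated correlation). For aged hearts it was -0.47, with 1 fallen and 6 adjusted over the list alone (adjusted p = 0.00197; adjusted p = 0.487 with an estimated correlation), a call lost under quantile normalization (0.0518). For aged western-diet hearts it was -0.39, with 4 fallen, also 4 adjusted over the list alone (adjusted p = 0.0315; adjusted p = 0.585 with an estimated correlation). That call was lost without C57 replicate 1 (0.066) or 3 (0.073) or aged western-diet replicate 4 (0.0594), under quantile normalization (0.239), with the atrial covariate (0.131) and with length and sex corrected together (0.0503). For the Hap-I mean it was -0.44, with 3 fallen and 9 adjusted over the list alone (adjusted p = 0.00188; adjusted p = 0.466 with an estimated correlation). The 13 mitochondrially encoded transcripts had 12 positive values in aged hearts with against without the diet, with 0 called over all genes or adjusted over the list alone and a median of 0.40 (adjusted p = 0.000581; adjusted p = 0.51 with an estimated correlation). Quantile normalization took that median to 0.07 and ended the call (0.151). Erythroid markers in the same comparison were positive in 6 of 6 genes, with 0 called over all genes or adjusted over the list alone (median 0.79, adjusted p = 0.00441; adjusted p = 0.51 with an estimated correlation).

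Kap, an androgen-regulated protein of kidney, was at 30.4 and 130.9 scaled TPM in aged western-diet replicates 4 and 5 and at 3.87 or less in the other 14 libraries. Gm10800 was at 351.7 in aged western-diet replicate 5 and at 47.1 or less elsewhere. The immunoglobulin gene Ighg2c was at 1.43 to 3.9 in C57 and at 6.31 to 16.9 in Hap-I hearts.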
